A study of Homo sapiens with 3 samples.

How the data were processed

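Total RNA of 3 samples of the HCC1937 cell line was extracted with Trizol, cleaned on columns and made into biotinylated cRNA, per the labels' protocols. The deposited mean bead intensity per probe was neither scaled between arrays nor background-subtracted, per the file headers and the values, and came with the number of beads and the standard error over beads, also in intensity units. The deposited detection p-value sets each probe against the negative controls of its array, per the file headers. A deposited second table holds intensity values on a linear scale. Its 3 columns had medians of 137.4, 137.5 and 137.5, and the ranks within each array equalled those of the bead intensities (Spearman correlation 1), so it appeared to be quantile normalized without background subtraction. This was inferred from the values, and the authors' software and settings are not given in the sources used here.

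The main values were made with limma 3.58.1 in R 4.3.3. The negative control distribution was inferred from the detection p-values, normexp background correction was applied with an offset of 16, and arrays were quantile normalized and put on a log2 scale. Later steps used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and figures used matplotlib 3.10.9. The offset and the background step set how far low values are drawn together, and quantile normalization assumes that the arrays share 1 distribution.

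Probes were named from the platform's annotation, which can be old. It listed 30117 probes, 30109 with 1 gene symbol and 8 with several, and the remaining 17198 probes were unnamed here. Gene identifiers of 30070 probes matched the RefSeq gene table of the GRCh38.p14 assembly, and 0 symbols changed. No coordinates were used. Each of the 20043 symbols was represented by the probe with the highest mean over the 3 arrays. A gene was measured in a comparison if that probe had a detection p under 0.01 on at least 1 of the 2 arrays. The undetected side was set to the lowest detected value of its array, or to its own value if higher, which makes the fold a bound. Where that left the undetected side brighter, the difference was set to 0.

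Groups came from the labels, with 1 array each, and 3 comparisons were made: dexamethasone against untreated, the combination against untreated, and the combination against dexamethasone. With 1 array per group no test was run and no p-value across genes is given. Genes were described by a fixed size rule, a log2 difference of at least 1. Per the labels' array identifiers, the untreated and combination arrays shared slide 1 and the dexamethasone array lay on slide 2. The standard error over beads was carried to the log2 difference from the background-corrected values. Most differences past the rule exceeded 3 bead standard errors, 1113 of 1118, 1200 of 1206 and 703 of 705 in the order of the comparisons. The median bead standard error of called genes was 0.13 in each comparison, so most genes past the rule exceed that limit by construction.

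The gene lists, comparisons, naming rule and alternatives were fixed before the data were examined. There were 28 lists of 557 genes, of which 43 had no named probe here. Each list's median difference was placed among the medians of 10000 random lists of the same size, drawn within 20 bins of mean level, as a description of these arrays. The naming rule took the 10 largest higher and 10 largest lower genes per comparison among those past the size rule with an official symbol and no detected probe in the other direction, up to 4 members past the rule from each list, 17 genes chosen in advance, and the 10 largest in each direction among genes past the rule in both comparisons with the untreated array. Some names were left out for length. ARRDC2, CRISPLD2, TFF3 and FOXA1 lie outside this rule and were named after their values were seen.

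The whole procedure was tested on simulated arrays for the comparison of dexamethasone with untreated, with 200 genes changed by known folds among 11509 measured. The noise was set to the spread between the combination and dexamethasone arrays (log2 SD 0.35 per array), which includes treatment effects. The changed genes were drawn from bright genes detected on both arrays. Recovery was therefore not tested for dim genes or for folds that are a bound. The 2-fold rule called 38.8% of the genes changed 2-fold, 91.0% of those changed 4-fold and 100% of those changed 8-fold. It also called 2.97% of 11309 unchanged genes, where noise of that size would give 4.26%. A first pass criterion of this test failed (over 90% recovery from 4-fold upwards in each direction, and under 2% of unchanged genes called). It was replaced, after the simulated result was seen, by closeness of the median to the simulated difference and an upper limit on unchanged genes called. That limit was set somewhat above the rate that the noise gives, and any lower rate passed. In the same step the simulated background spread was re-estimated, and no value from the real arrays depends on either change.

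Alternatives were the deposited normalized values, quantile normalization without background correction, scaling to the 75th percentile, an offset of 50, a detection p under 0.05, detection on both arrays, no detection filter, no bound on the undetected side, the median over a gene's probes, and size rules of 1.5-fold and 3-fold. Without the detection filter, probes undetected on both arrays kept their own values, a detail settled after the data were examined.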

Results

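HCC1937 is an established human breast cancer cell line, which the labels class as basal. It was grown in DMEM with 3 mM glucose and 0.5 mM glutamine. Total RNA was profiled on 3 Illumina bead arrays of 47315 probes: 1 array from untreated cells, 1 from cells given the synthetic glucocorticoid dexamethasone at 200 nM for 16 h, and 1 from cells given 200 nM dexamethasone together with 1 µM retinoic acid for 16 h. The title frames the work as hormonal and nutritive control of plasticity in this line. The untreated array carried 16818 detected probes, the dexamethasone array 17091 and the combination array 16635, at a detection p-value under 0.01. Their median unnormalized intensities were 131.6, 149.3 and 159.0, with a median of 22, 21 and 22 beads behind each probe. Each group held 1 array, so no difference below has a replicate check, and the number of arrays limits the precision of every value. The bead standard error (SE) printed beside a log2 difference covers only the spread between beads within the arrays. A gene is called higher or lower where its normalized log2 values differed by at least 1, a 2-fold difference. "At least" marks a gene detected on only 1 of the 2 arrays compared, whose fold was computed against the lowest detected value of the other array.

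The first comparison asked which transcripts differed after dexamethasone alone. Genes induced by the glucocorticoid receptor were higher as a group. Of the 28 measured members of that list, 15 were higher on the dexamethasone array and 2 were lower (median log2 difference 1.36, percentile 100 among 10000 random lists matched on mean level). Without the detection filter the median was 0.90. SGK1, a kinase that promotes epithelial sodium uptake, was 43.0-fold higher (log2 difference 5.43, bead SE 0.09), and KLF9, a transcription factor, was 19.1-fold higher (4.25, bead SE 0.12). FKBP5, a co-chaperone of steroid receptors, was 9.92-fold higher, DUSP1, a phosphatase of MAP kinases, 9.43-fold, and TSC22D3, the leucine zipper protein GILZ, 7.12-fold. PER1 was detected on the dexamethasone array alone of this pair, where it was at least 1.64-fold higher, and ARRDC2 and CRISPLD2 were the 2 lower members, though the other detected probe of ARRDC2 differed in the opposite direction. The receptor itself, NR3C1, differed by 0.15 (bead SE 0.17), and by -0.32 on its other detected probe.

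Basal and myoepithelial markers were higher after dexamethasone. Of 16 measured, 8 were higher and 0 lower (median 0.92, percentile 100). The median was 0.44 among genes detected on both arrays, 0.49 with the deposited normalized values and 0.29 without the detection filter, with percentiles of 99.0 or higher. KRT16 was at least 95.9-fold higher, CRYAB at least 11.6-fold and KRT5 at least 7.54-fold, and all 3 were undetected on the untreated array. SNAI2, a transcription factor linked to basal identity and mesenchymal transition, was 6.65-fold higher (4.36-fold on its other detected probe). KRT6C was at least 207-fold higher, the largest difference under the naming rule, but its sequence is nearly identical to KRT6A and KRT6B, and KRT16P2 (63.9-fold higher) is a pseudogene close to KRT16, so neither signal can be assigned to 1 gene with certainty. KRT14 was undetected on all 3 arrays.

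Luminal markers gave a mixed picture. Of 26 measured, 2 were higher and 6 lower, with a median of -0.13 (percentile 13.0) that did not stand apart from random lists. ESR1, GATA3, FOXA1 and TFF1 were detected on all 3 arrays, and TFF1 had an unnormalized intensity of 17170 on the untreated one. HCC1937 is usually described as lacking the estrogen receptor, which these values do not match, and the identity of the line was not checked here. AGR2 was 5.70-fold lower, the estrogen receptor gene ESR1 3.33-fold lower and the luminal transcription factor GATA3 3.00-fold lower. TFF3 and FOXA1 were also lower, by log2 differences of -1.52 and -1.30, whereas KRT7 was 3.24-fold higher. The simple-epithelium keratin KRT8 differed by 0.40, within 2-fold. KRT18 differed by -0.95 on its brightest probe and by 0.57 on its other detected probe, so its direction is not settled.

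Genes of the inflammatory list, fixed as genes that glucocorticoids repress, were mostly not lower. Of 14 measured, 5 were higher and 1 lower (median 0.39, percentile 99.0). Only 8 of the 29 named members were detected on the untreated array. Members undetected there could not be called lower, so these counts are a limited check on repression. The chemokine CCL20 was at least 4.28-fold higher, CXCL8 3.86-fold higher (1.64-fold on its other probe) and TNF at least 3.00-fold higher, and IL24 was at least 3.38-fold lower. The percentile was 94.1 among genes detected on both arrays, and the median ranged from 0.23 with the deposited values to 0.64 without the bound on undetected genes. Of 28 measured proliferation genes, 10 were lower and 0 higher (median -0.73, percentile 0). RRM2, a subunit of ribonucleotide reductase, was 3.83-fold lower, the replication licensing gene MCM7 2.81-fold and the thymidine kinase TK1 2.64-fold. Of 12 measured genes of epithelial ion transport, 5 were higher and 1 lower (median 0.81, percentile 100, but 0.38 and 97.0 among genes detected on both arrays), among them the sodium channel subunits SCNN1G (at least 10.5-fold) and SCNN1B (at least 5.33-fold). Of 13 measured immediate early genes, 7 were higher and 2 lower (median 1.24, percentile 100, but 0.30 and 95.5 among genes detected on both arrays). FOS was at least 7.37-fold higher, ATF3 at least 6.81-fold higher and EGR3 4.87-fold lower. Cholesterol synthesis genes had a median of -0.60 (percentile 0), with 2 of 18 lower, INSIG1 by 2.46-fold and DHCR7 by 2.02-fold (1.85-fold on its other detected probe).

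In all, 622 of 10852 measured genes were at least 2-fold higher and 496 at least 2-fold lower on the dexamethasone array. Outside the lists, the calcium-binding protein gene S100P was 87.7-fold higher, the potassium channel gene KCNK12 at least 142-fold, the muscle atrophy ubiquitin ligase FBXO32 74.5-fold and pepsinogen C (PGC) at least 71.7-fold. SPTSSB, a subunit of serine palmitoyltransferase, was 25.5-fold lower, and the BMP and activin inhibitor BAMBI 7.31-fold. The receptor tyrosine kinase RET, of the retinoic acid list, was 7.16-fold lower. Without background correction the counts were 306 and 177. Where a called gene had other detected probes, 366 of these 395 probes (92.7%) differed in the same direction, against 70.9% of the other probes of genes not past the rule. The dexamethasone array was the only one on slide 2. Of the genes called here, 274 higher and 258 lower ones also passed the rule in the same direction between the untreated and combination arrays, which shared slide 1, so for these a difference was seen within a slide. That pair also differed by retinoic acid and used the same untreated array, so it does not isolate dexamethasone. For the other genes slide and treatment cannot be told apart.

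**Figure D1:**
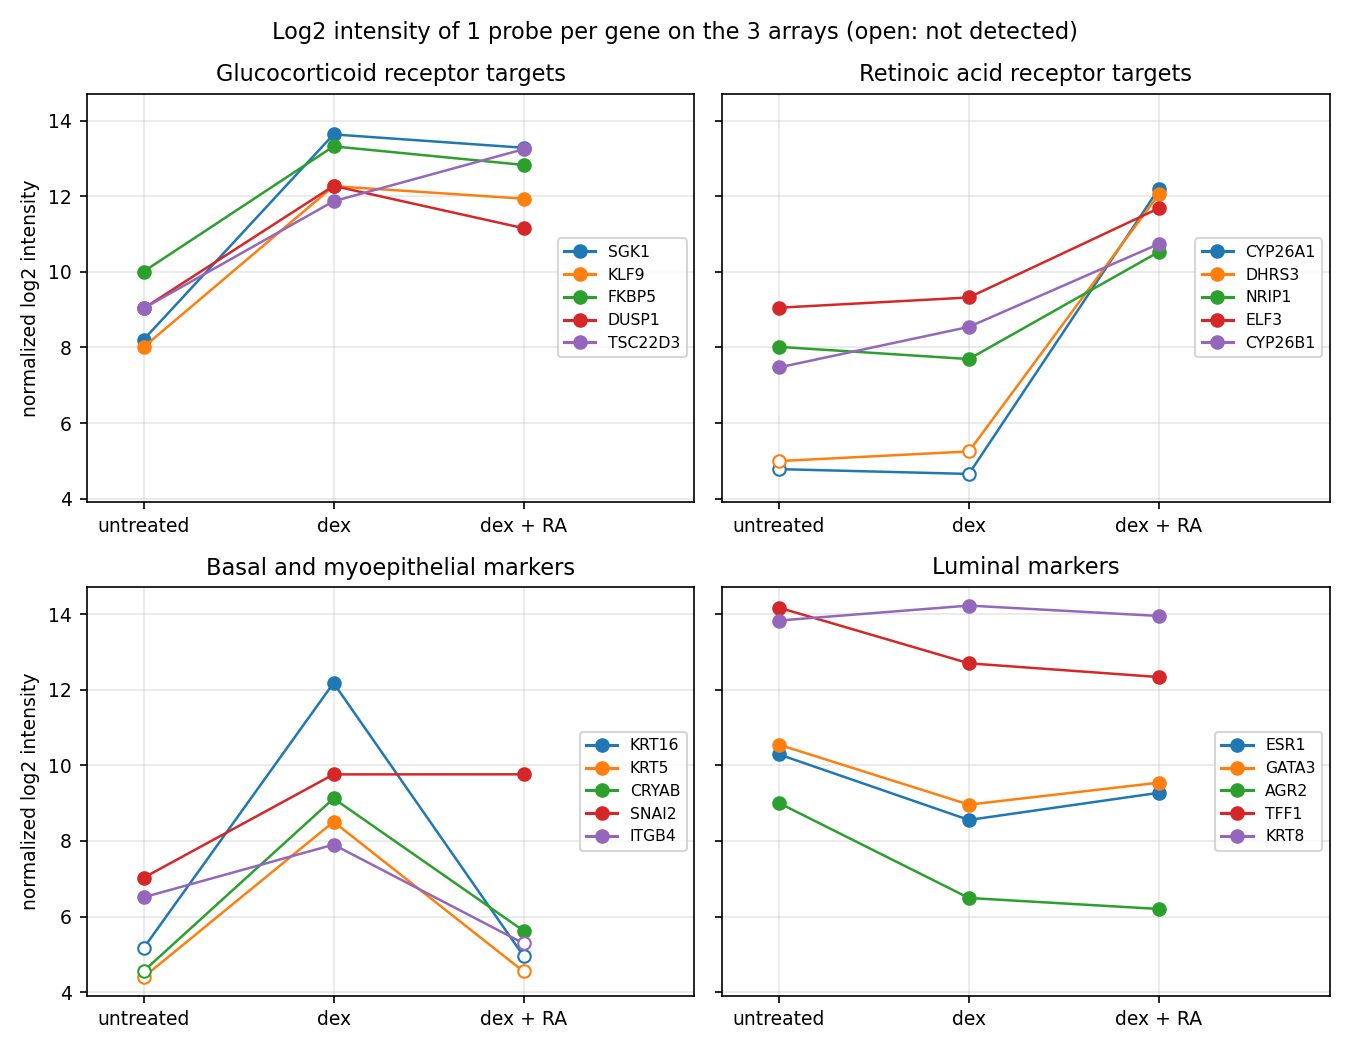
Normalized log2 intensity (y axis) of 5 genes from each of 4 gene lists on the untreated, dexamethasone (dex) and dexamethasone + retinoic acid (dex + RA) arrays (x axis), with 1 point per array and open points where the probe was not detected. The genes were picked for display and do not represent their lists. RET, RARA, CDH3 and FSCN1, lower with the combination than on the untreated array, are not shown. Of 26 measured luminal markers, 18 were within 2-fold after dexamethasone. KRT16 reached 12.18 on the dexamethasone array and was undetected on the other 2, and CYP26A1 reached 12.20 on the combination array and was undetected on the other 2.

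The second comparison set dexamethasone together with retinoic acid against the untreated array. Here the retinoic acid receptor targets joined the glucocorticoid targets. Of 16 measured retinoic acid targets, 8 were higher and 2 lower (median 0.74, percentile 100, but 0.37 and 96.0 among genes detected on both arrays). CYP26A1, which degrades retinoic acid, was at least 97.3-fold higher, DHRS3, a retinaldehyde reductase, at least 87.8-fold, CYP26B1 9.62-fold and the epithelial transcription factor ELF3 6.19-fold. CYP26B1 was also the 1 member of this list called higher after dexamethasone alone. The other detected probes of CYP26A1 were 10.4-fold and 45.5-fold higher, against undetected values. The 2 lower members were RET (6.02-fold) and the receptor gene RARA (2.31-fold). RARB, a classical target, was undetected on all 3 arrays. Of 27 measured glucocorticoid receptor targets, 18 were higher and 2 lower (median 1.58, percentile 100), led by SGK1 (33.7-fold), TSC22D3 (18.5-fold), KLF9 (15.2-fold) and FKBP5 (7.06-fold).

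Of 13 measured basal markers, 3 were higher and 2 lower (median -0.45, percentile 1.94). This median lay inside the central 95% of random lists under 5 of 9 alternatives, with -0.17 for the deposited values (percentile 8.78) and -0.05 without the detection filter (percentile 27.1). SNAI2 was 6.65-fold higher (2.75-fold on its other detected probe) and LAMB3 2.62-fold higher. The adhesion gene CDH3 was 3.33-fold lower and FSCN1 2.36-fold lower, and KRT5 and KRT16 were undetected on both arrays. Of 26 luminal markers, 1 was higher and 7 lower (median -0.60, percentile 0.01, and -0.39 by the median over probes). AGR2 was 6.97-fold lower, TFF1 3.57-fold and ELF5 3.52-fold, ESR1 and GATA3 were 2.02-fold and 2.01-fold lower, and KRT7 was 3.46-fold higher. Of 28 proliferation genes, 6 were lower and 0 higher (median -0.66, percentile 0), among them BIRC5 (2.93-fold) and the mitotic kinase PLK1 (2.61-fold). Of 10 measured mesenchymal genes, 5 were higher and 2 lower (median 1.14, percentile 100), with TAGLN 3.58-fold higher and S100A4 3.10-fold lower. After dexamethasone alone 5 of 12 were higher and 0 lower (median 0.61, percentile 100). Without the detection filter the mesenchymal medians were 0.03 and 0.00, inside the central 95% of random lists. The inflammatory list had 4 of 12 higher and 0 lower (median 0.67, percentile 99.9), with IL24 8.33-fold higher. Its median was 0.24 with the deposited values (percentile 99.2) and 0.31 among genes detected on both arrays (percentile 92.5). Members of that list undetected on the untreated array could again not be called lower.

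Altogether 625 of 10705 measured genes were at least 2-fold higher and 581 at least 2-fold lower. S100P was 99.0-fold higher, PGC at least 67.7-fold, the hypoxia-inducible factor gene EPAS1 at least 53.1-fold and the protease gene TMPRSS2 at least 42.3-fold. S100A7 was 36.7-fold higher and its near copy S100A7A at least 37.2-fold, which probes may not tell apart. SPTSSB was 28.4-fold lower, the morphogen gene BMP7 14.4-fold, TGFB3 11.4-fold and the growth factor receptors FGFR3 and FGFR4 9.28-fold and 8.82-fold. Of all calls 51.8% were higher. With arrays scaled to their 75th percentile in place of quantile normalization, which moved the median of all genes from -0.01 to -0.12, that share was 38.3%.

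**Figure D2:**
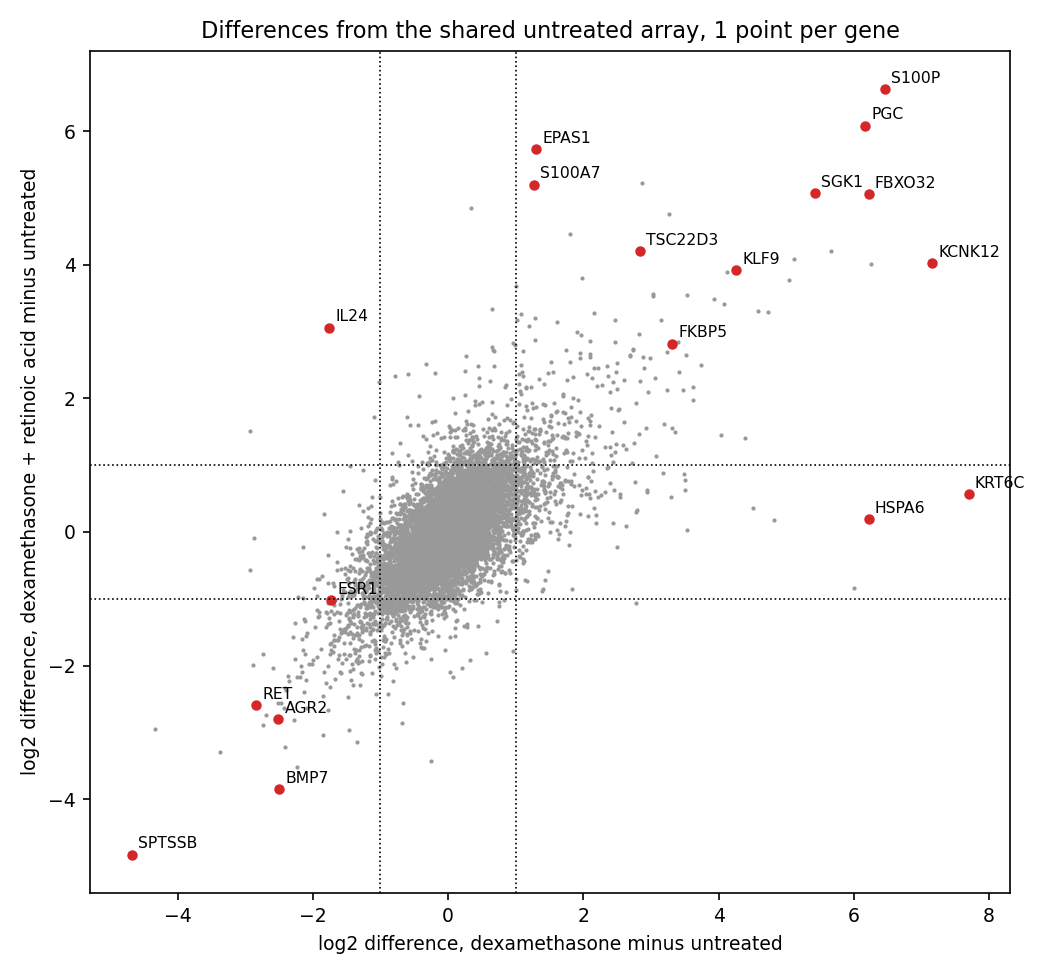
Log2 difference from the untreated array of the dexamethasone array (x axis) and of the combination array (y axis), 1 point per gene measured in both comparisons, with dotted lines at the 2-fold rule and values against an undetected array drawn at their bound. S100P lies high on both axes (6.45 and 6.63), KRT6C and HSPA6 lie high on the x axis alone, and IL24 lies at -1.76 and 3.06.

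The third comparison, dexamethasone + retinoic acid against dexamethasone, asked what retinoic acid added. Of 15 measured retinoic acid receptor targets, 7 were higher and 0 lower (median 0.83, percentile 100). The median was 0.53 among genes detected on both arrays, 0.48 with the deposited values and 0.25 without the detection filter, with percentiles of 99.9 or higher. CYP26A1 was at least 100.3-fold higher, DHRS3 at least 90.5-fold, NRIP1, a nuclear receptor corepressor, 7.13-fold (log2 difference 2.83, bead SE 0.13), ELF3 5.13-fold and the retinol transporter STRA6 at least 3.47-fold. The other detected probes of CYP26A1 were 12.5-fold and 46.2-fold higher, against undetected values. Basal markers were lower on the combination array than on the dexamethasone array. Of 16 measured, 0 were higher and 7 lower (median -0.72, percentile 0, and -0.46 without the detection filter). KRT16 was at least 94.0-fold lower, CRYAB 11.3-fold, KRT5 at least 7.39-fold and the integrin ITGB4 at least 4.86-fold. KRT6C, subject to the same doubt as above, was 140.0-fold lower.

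Luminal markers were lower rather than higher as a group, with 1 of 26 higher and 5 lower (median -0.25, percentile 0.37, and -0.51 with scaling to the 75th percentile). ELF5, a transcription factor of alveolar progenitors, was 5.19-fold lower, ERBB3 2.84-fold (1.14-fold on its other detected probe), the prolactin receptor gene PRLR 2.55-fold and SPDEF 2.37-fold. XBP1 was 2.06-fold higher (1.82-fold on its other detected probe). ESR1 differed by 0.72 and GATA3 by 0.58, within 2-fold. Glucocorticoid receptor targets had a median of -0.31 (percentile 0.08), with 3 of 28 higher and 2 lower. TSC22D3 was 2.59-fold higher and SCNN1A 3.53-fold higher, DUSP1 was 2.17-fold lower and RASD1 4.73-fold lower, and SGK1, KLF9 and FKBP5 differed by -0.35, -0.33 and -0.49. Immediate early genes had 4 of 13 lower and 0 higher (median -0.54, percentile 0.03, but -0.19 and 4.84 with the deposited values), with ATF3 4.07-fold and EGR1 2.61-fold lower.

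In this comparison 321 of 10734 measured genes were at least 2-fold higher and 384 at least 2-fold lower. The arrays lay on different slides, and 174 of the higher and 87 of the lower genes also passed the rule in the same direction within slide 1, against the untreated array. TMPRSS2 was at least 43.6-fold higher, the interleukin gene IL24 at least 28.2-fold and IL20 21.7-fold, the endothelial cadherin gene CDH5 at least 25.9-fold, DLK2 22.8-fold and EPAS1 21.5-fold. The other detected probes of IL24 and DLK2 were 8.18-fold and 7.81-fold higher, against undetected values. HSPA6 was 65.2-fold lower and HSPA7 24.8-fold lower, though these 2 sequences are nearly identical, and DDC, which makes dopamine and serotonin, was 17.7-fold lower. Of all calls 45.5% were higher, and 24.8% with the scaling to the 75th percentile (201 higher and 608 lower), under which the median of all genes was -0.15.

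Across the 3 arrays, 274 genes were higher and 258 lower on both treated arrays than on the untreated one. Both differences used the same untreated array. Independent lists of the observed sizes would share 34.7 and 27.6 genes. Simulated unchanged arrays gave 41.4 and 41.4, so part of the overlap may come from the shared array. Their noise was equal and normal on each array, set from the combination and dexamethasone pair, without the normalization, filter or bound. Over measured genes the log2 differences had SDs of 0.49 and 0.57 against untreated and 0.44 for that pair. The simulated noise (0.35 per array) was set over probes without the bound, so it does not correspond to that 0.44. Carried to a difference between arrays, it was about as wide as the spread after dexamethasone and narrower than that with the combination. The simulated counts are only a rough guide. Genes higher on both treated arrays included S100P, SGK1, FBXO32, the proapoptotic gene BMF (at least 34.8-fold after dexamethasone and at least 17.0-fold with the combination) and 15 glucocorticoid receptor targets. Genes lower on both included SPTSSB, BMP7, the protocadherin gene PCDH19, the apoptosis inhibitor gene BCL2 (4.02-fold and 3.95-fold) and 5 luminal markers. On the dexamethasone array, 179 genes were higher and 60 lower than on both others, and on the combination array 174 were higher and 87 lower. The simulated unchanged arrays gave 41.2 and 41.5 for dexamethasone, and 40.7 and 41.3 for the combination.

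**Figure D3:**
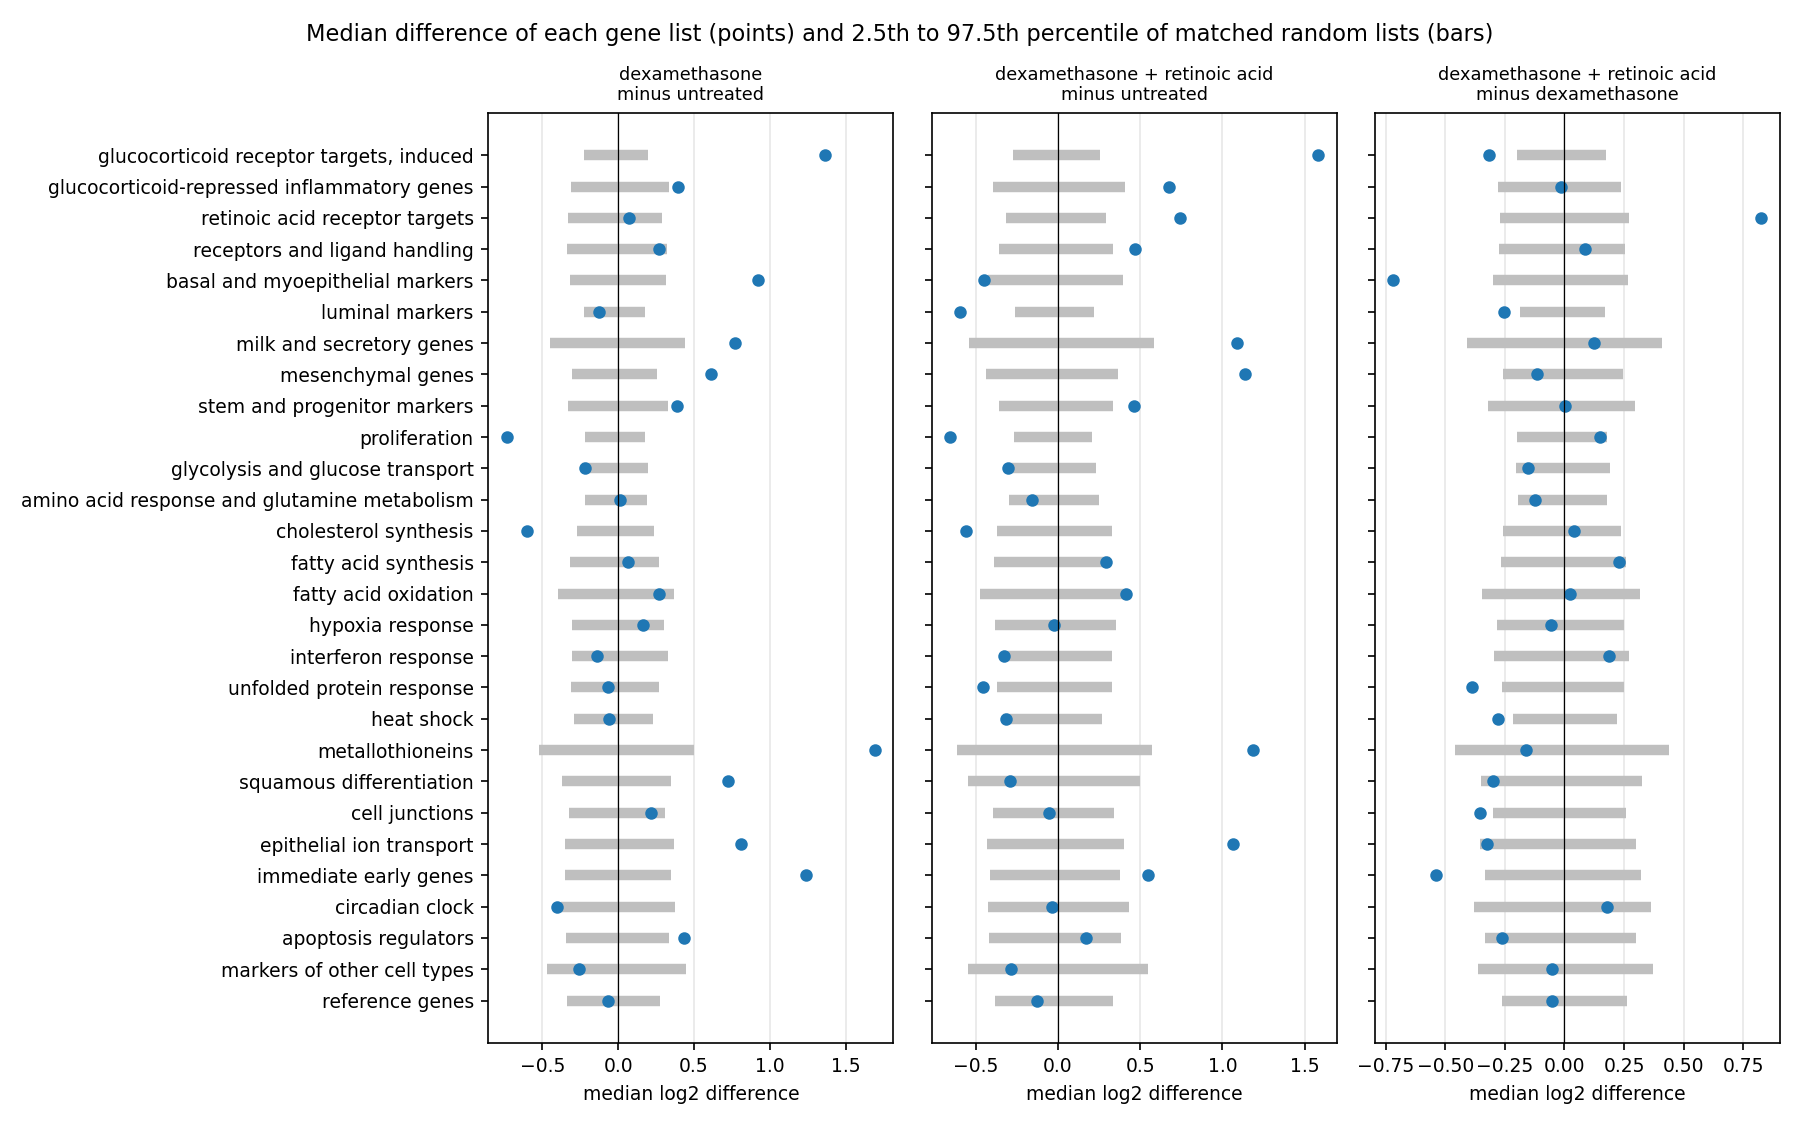
Median log2 difference (x axis) of each of the 28 gene lists (y axis) in the 3 comparisons, as points, with bars over the central 95% of the medians of 10000 matched random lists. Glucocorticoid receptor targets lie at 1.36 and 1.58 against the untreated array, and basal markers lie at 0.92 after dexamethasone and at -0.72 in the combination against dexamethasone. Both basal values use the same dexamethasone array.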

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

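Of 2587 values of genes under the naming rule, 2412 kept their side of the 2-fold rule, 170 kept the direction but not the size and 5 moved past the rule. The 2427 values of genes past the rule had 0 changes of sign and the 160 others had 2, for KRT8 with the combination and KRT18 in the last comparison. Over all genes past the rule, 26815 values were measured under the alternatives to the normalization, filters, bound and probe choice, and 5 changed sign. MAFF, higher in the last comparison (1.22), was at -0.08 with the deposited values and without background correction. By the median over probes TBC1D24 went from 1.16 to -0.04 and ZMAT3 from -1.09 to 0.75 after dexamethasone, and MANEA, 2.31-fold higher with the combination, was at -0.11. These 4 genes were named after their values were seen, and the cause was not tested. Counts, in the order dexamethasone against untreated, combination against untreated and combination against dexamethasone, moved by over 1.5 times as follows. The deposited values gave 289, 259 and 105 genes higher and 165, 221 and 145 lower, and quantile normalization without background correction 306, 272 and 108 higher and 177, 241 and 153 lower. Both keep the background in the signal, which shrinks folds by construction. An offset of 50 gave 325 lower in the first comparison and 199 higher in the last, for the same kind of reason. Scaling to the 75th percentile gave 201 higher and 608 lower in the last comparison, where the median of all genes moved to -0.15. A 1.5-fold rule gave 1450, 1656 and 1131 higher and 1482, 1726 and 1233 lower, and a 3-fold rule 243, 209 and 78 higher and 112, 153 and 88 lower, by construction. The detection filters, the bound and the median over probes kept each count within 1.5 times. The inflammatory list after dexamethasone kept its median of 0.39 among genes detected on both arrays, at percentile 94.1 in place of 99.0, and the cause was not tested. The other planned list medians kept their direction and their place inside or outside the central 95% of random lists, but several moved by over 1.5 times. After dexamethasone, basal markers (0.92) had 0.49 with the deposited values, 0.55 without background correction, 0.44 among genes detected on both arrays and 0.29 without the detection filter. Glucocorticoid targets (1.36) had 0.90 without that filter, luminal markers (-0.13) had -0.20 with scaling to the 75th percentile, and the inflammatory list had 0.23 with the deposited values, without background correction and at a detection p under 0.05, and 0.64 without the bound. In the last comparison, retinoic acid targets (0.83) had 0.48 with the deposited values, 0.51 without background correction, 0.53 both at a detection p under 0.05 and among genes detected on both arrays, and 0.25 without the filter, basal markers (-0.72) had -0.46 without the filter, and luminal markers (-0.25) had -0.51 with the scaling. Of 682 values of the 76 other list medians, 33 kept the direction but moved inside the central 95%, and 24 moved outside it. Of 279 values of the 31 medians outside it, 2 changed sign: receptors and ligand handling, at 0.47 with the combination, had -0.31 among genes detected on both arrays and -0.036 without the filter, and the cause was not tested. Of 403 values of the 45 medians inside it, 20 changed sign, for 12 medians of at most 0.28 in size. Signal over background limits genes near the detection limit, where 186, 177 and 83 calls rest on a bound, and leaving out an array was not possible with 1 array per group.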

Other observations

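Of the further gene groups, some stood apart from random lists and others did not. Of 5 measured metallothioneins, metal-binding proteins induced by glucocorticoids and metals, 4 were higher and 1 lower after dexamethasone (median 1.69, percentile 100) and likewise with the combination (median 1.19, percentile 100). MT1G was 4.27-fold and 6.16-fold higher and MT1F 2.41-fold and 4.35-fold lower, although probes may not separate these close paralogs. Desmosome and tight junction genes included 4 higher of 14 in each comparison with untreated, with DSP 5.42-fold higher after dexamethasone and CLDN1 5.64-fold higher with the combination, but the list medians (0.22 and -0.06) lay among random lists, except for 0.33 (percentile 98.6) after dexamethasone by the median over probes, which also turned the second to 0.06. In the combination against dexamethasone their median was -0.36 (percentile 1.01), with 1 of 14 higher and 1 lower. That median lay outside the central 95% of random lists under 6 of 9 alternatives. Stem and progenitor markers had 4 of 14 higher and 0 lower after dexamethasone (median 0.38, percentile 98.9) and 5 higher and 1 lower with the combination (median 0.46, percentile 99.5). These medians lay inside the central 95% of random lists under 2 of 9 alternatives each, with 0.23 (percentile 89.1) after dexamethasone among genes detected on both arrays and 0.20 (percentile 97.4) with the combination under scaling to the 75th percentile. KLF4 was 7.17-fold and 4.81-fold higher and KRT15 at least 5.11-fold and at least 5.57-fold higher. Of 7 measured milk and secretory genes, 3 were higher after dexamethasone (median 0.77, percentile 99.9, but 0.24 with the deposited values and 0.02, percentile 67.2, without the detection filter), with CEL 3.50-fold and MFGE8 2.67-fold higher. Unfolded protein response genes had a median of -0.39 in the combination against dexamethasone (percentile 0.17), with 12 of 14 within 2-fold. HSPA5 was lower (log2 difference -1.32) and XBP1 2.06-fold higher (1.82-fold on its other detected probe). Fatty acid synthesis genes did not stand apart, with medians of 0.07 after dexamethasone (percentile 72.6, 3 of 12 higher and 1 lower) and 0.29 with the combination (percentile 96.3, 4 higher and 0 lower). After dexamethasone the desaturase FADS1 was 4.61-fold and the elongase ELOVL5 2.88-fold higher, and the elongase ELOVL6 was 2.72-fold lower. Reference genes differed little, with medians of -0.07, -0.13 (-0.37 with scaling to the 75th percentile) and -0.05 and 0 of 10 past the rule in each comparison.

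The tests below of genes with 1 detected probe, of the slide, of culture stress and of another line on the untreated array were chosen after the results were seen, as was the reading that the heat shock test, set in advance on both comparisons, leaves its explanation open.

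Genes on which the dexamethasone array stood at least 2-fold apart from both others (179 higher and 60 lower), among them the basal keratins, were weighed against 2 technical explanations. Faults of particular probes are argued against, as a set, for the 65 genes with another detected probe, KRT16 among them. Of their 77 other detected probes, 71 (92.2%) differed from both other arrays in the same direction. The share was 58.7% of 2106 other probes of genes on which this array was highest or lowest without standing 2-fold apart. The smaller differences of those genes lower that share by construction, and only direction was counted, not size. Probe faults stay open for the other 174 of the 239 genes, among them KRT5, KRT6C and CRYAB. The slide stays open too, because this array was the only one on its slide. The 2 arrays that shared a slide had a correlation across genes of 0.93 (Spearman, 14821 probes detected on all arrays), the lowest of the 3 pairs (0.94 and 0.96 for the others). It was the middle one over probes detected on at least 1 array, genes are not independent replicates, and treatment effects also enter these values. Loss of a dexamethasone effect when retinoic acid is present is a possible explanation and cannot be told apart from the slide.

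HSPA6 was at least 74.5-fold higher on the dexamethasone array than on the untreated one and 65.2-fold higher than on the combination array, and its near copy HSPA7 followed. On its other detected probe these folds were 2.66 and 6.54. A general heat shock response in that culture stays open. The other 11 heat shock genes had a median of -0.18 there against untreated (percentile 12.7), which goes against it. In the combination against dexamethasone their median was -0.24 (percentile 1.72), the direction that it predicts. The full list of 12, HSPA6 included, was also low in the combination against untreated (median -0.32, percentile 3.26, 0 higher and 1 lower). The -0.24 can therefore not be read as high values on the dexamethasone array. The limit set in advance for excluding it named the first comparison alone, where members went both ways (DNAJB1 by 1.21 and HSPA1A by -0.70), so that median does not decide. A wider stress of that culture stays open too. The immediate early genes had a median of -0.54 in the combination against dexamethasone (percentile 0.03). It was -0.19 with the deposited values and -0.20 without background correction, inside the central 95% of random lists. Against untreated their medians were 1.24 after dexamethasone (percentile 100) and 0.55 with the combination (percentile 99.5). These lay inside the central 95% under 1 and 4 of 9 alternatives. Stress would also not be separated from treatment or slide by these medians.

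The untreated array of this line, labelled basal, detected 26 of the 29 named luminal markers, among them ESR1, GATA3, FOXA1 and TFF1, while KRT5, KRT14 and KRT16 were undetected. All 3 arrays detected 100% of these 26 luminal markers, which argues against treated arrays from a line that lacks them. Another line with luminal markers would also detect them, so detection cannot decide whether the untreated array alone came from another line. It also does not bear on a culture of the same line with a wrong label. HCC1937 is usually described as lacking the estrogen receptor, so the ESR1, GATA3 and TFF1 signal on all 3 arrays goes against the named line. Another line in all 3 cultures was not tested and stays open, and so does what each luminal value says of HCC1937. No biological explanation was tested.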
